A study of Mus musculus with 12 samples.

How the data were processed

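Astrocyte TRAP (translating ribosome affinity purification) was applied to somatosensory cortex of male mice at postnatal day 40, per the labels' protocols. An eGFP-tagged ribosomal protein driven by the astrocyte promoter Aldh1l1 was pulled down with anti-eGFP beads, and the ribosome-bound RNA was made into stranded total-RNA libraries after ribosomal RNA depletion. The labels give the genotypes as Fmr1 knockout and wild type on a mixed FVB and C57 background. Fmr1 encodes FMRP, the RNA-binding protein lost in fragile X syndrome. The labels hold 12 entries, which are 6 library numbers (13 to 18) with 2 entries each. Libraries 14, 16 and 18 are knockout and libraries 13, 15 and 17 are wild type. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries only.

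The deposited count table holds RSEM expected counts for 52550 features in each of the 12 entries, per the file headers, with no scaling. STAR 2.5.3a, RSEM 1.3.0, edgeR and the genome build mm10 are named in the submitters' processing notes, and the strand setting and the annotation release are not given in the sources used here. The authors' deposited comparison table lists 14843 features with a log2 fold change, a mean log2 CPM, a p-value, an adjusted p-value and a scaled signal per entry. Its fold changes are knockout over wild type, read from the sign of Fmr1. The scaled signal of the authors' deposited table matched CPM with TMM scaling recomputed on the 12 entries, for features over a CPM of 1 in at least 2 entries, with a largest difference of 5e-04. The logarithms of its p-values correlated across genes at 0.996 with those of edgeR's classic exact test on the 12 entries, although the test the authors ran is not given in the sources used here.

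The 2 entries of each library were compared by a chi-square test over features with a summed count of at least 20. The median chi-square per feature lay between 0.467 and 0.495 within libraries, against 2.93 to 18.8 between first entries of different libraries of 1 group, and the chi-square per degree of freedom lay between 1.17 and 2.33 against 17.8 to 406. For most features the entries of a library therefore differed by about the sampling noise. They were summed, rounded to whole numbers and counted as 1 sample, which gave 3 knockout and 3 wild-type libraries.

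Total summed counts ran from 10953958 in knockout library 16 to 22397202 in wild-type library 15. Genes were filtered with filterByExpr on genotype, which left 14990, and scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. It had 4 residual and 8.24 total degrees of freedom, with a common biological coefficient of variation of 0.261. Values per gene are TMM-scaled CPM as mean ± SD over libraries, and the SE of a log2 fold change was taken from the F statistic. The exact permutation test over 6 libraries cannot give a two-sided p below 0.1.

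Counts of 14990 genes were simulated with the means, library sizes and dispersions of these libraries. Known changes were given to 100 genes at 2-fold and 100 at 4-fold, all with a mean log2 CPM over 1. The quasi-likelihood test called 44% of the genes changed 2-fold and 83% of those changed 4-fold. It made 14 false calls. DESeq2 1.42.0 called 67% and 94% with 52 false calls. Differences between libraries beyond size and dispersion were not simulated, so these percentages need not hold for the real libraries. In simulated data without a change no list was called, and a list raised by 1 log2 unit was called together with 1 other list. The simulated genes were drawn independently, while members of real lists move together, with an estimated correlation of 0.90 for the oligodendrocyte markers. The simulation therefore cannot show how list tests behave on correlated members.

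The 28 gene lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, each adjusted over the 28 lists. The lists were astrocyte, neuron, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural and fibroblast, and choroid plexus and ependymal markers, blood cell genes, mGluR5 signalling, glutamate and GABA handling, potassium, water and gap junction genes, pan-reactive, A1 and A2 astrocyte genes, cholesterol synthesis, synapse-regulating genes, reported FMRP-bound transcripts, FMRP family and partners, cytosolic ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, immediate early genes, clock genes, glucocorticoid and metallothionein response, heat shock and unfolded protein response, long noncoding RNAs and strain-variable genes. Groups, lists, designs and the rule for named genes were fixed before the data were examined. The rule names Fmr1, Grm5, R3hdm1 and Arpp21, then up to 10 genes per direction, taken by smallest p where too few passed the threshold, with a mean log2 CPM of at least 1, all 3 knockout libraries on 1 side of all 3 wild-type libraries and predicted genes left out. It also names up to 4 members per list with the smallest p and up to 5 genes within 10 Mb of Fmr1 that pass the threshold. Of the genes the rule takes, 1 is not reported here.

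Positions come from RefSeq genes of GRCm38.p6, the assembly behind mm10, in which 14018 of the 14990 tested genes were found by symbol. The planned test of genes with miR-128 seed matches was not run, since no transcript sequences were used here. Alternatives covered the treatment of entries, other scalings, filters and tests, the month in the library names (5 or 6) as a covariate, and leaving out each library. DESeq2's Wald test and limma voom were among the alternatives chosen beforehand, and edgeR's exact test was added after the data were seen.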

Results

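Ribosome-bound RNA of cortical astrocytes was compared between Fmr1 knockout and wild-type mice, 3 libraries each. The series asks how loss of FMRP in astroglia changes their RNA, with miR-128 and the glutamate receptor mGluR5 named in its title. Total counts were 15760052, 10953958 and 21696862 in knockout libraries 14, 16 and 18, and 19787520, 22397202 and 21188758 in wild-type libraries 13, 15 and 17. Each library was deposited as 2 entries that for most features differed by about the sampling noise, and the pair was counted as 1 sample.

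Among the cell type marker lists, the astrocyte markers had the highest median level. The 24 astrocyte markers had a median level of 620 CPM over the 6 libraries, against 86.2 CPM for the 24 neuron markers and 2.08 CPM for the 19 microglia markers. These levels depend on the genes chosen, so they do not give the share of RNA from each cell type. Reads of ribosomal RNA are known to collect on the features CT010467.1, Lars2 and AY036118. These 3 features held 35.6% and 45.1% of the counts in knockout libraries 14 and 16 and 0.892% in knockout library 18. In wild-type libraries 13, 15 and 17 they held 0.939%, 7.45% and 1.75%. Without them the counts of libraries 14 and 16 were 10146188 and 6012112, against at least 19601657 in the other libraries.

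**Figure D1:**
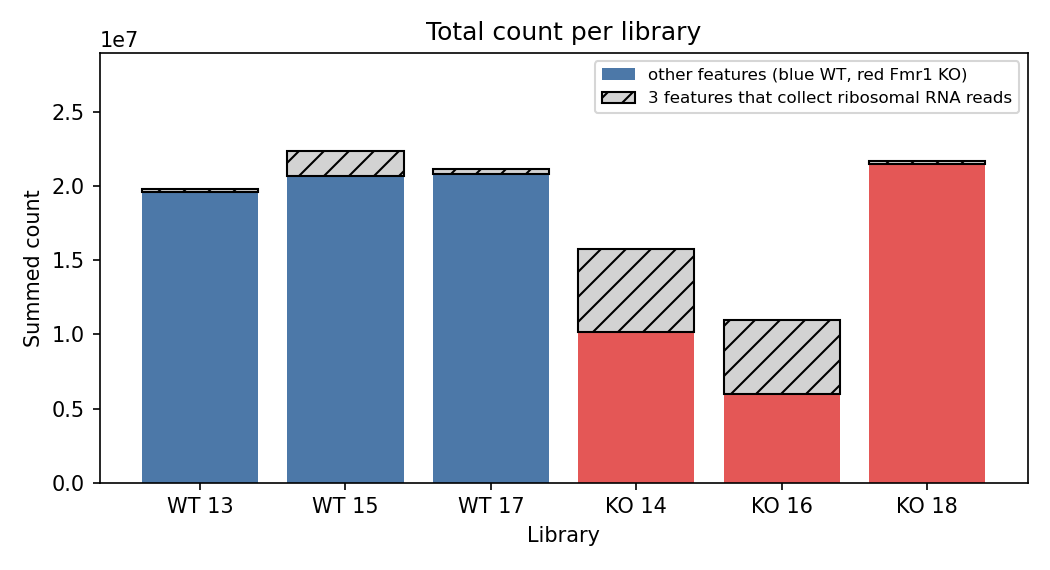
Total summed count per library (vertical axis, in counts) for the 3 wild-type libraries in blue and the 3 knockout libraries in red, with the part on 3 features that collect ribosomal RNA reads hatched. The hatched part is 35.6% and 45.1% of knockout libraries 14 and 16 and at most 7.45% of the other libraries.

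Fmr1, the knocked-out gene, was low in every library labelled knockout. Its level was 4.32, 4.22 and 1.32 CPM in knockout libraries 14, 16 and 18, and 31.6, 38.4 and 37.0 CPM in wild-type libraries 13, 15 and 17. The means were 3.29 ± 1.71 and 35.7 ± 3.58 CPM (SD, n = 3 each), 11.5-fold lower in the knockout (log2 fold change -3.53, SE 0.41). Fmr1 lies on chromosome X from 68678536 to 68717963 (mm10). The edgeR quasi-likelihood test gave Fmr1 the smallest p of all genes, with an adjusted p of 0.2998 that missed the threshold. Fmr1 passed with DESeq2 (adjusted p = 5.07e-18) and edgeR's exact test (adjusted p = 1.68e-11). Limma voom gave an adjusted p of 0.148. The exact permutation p of Fmr1 was 0.1, the smallest that 3 libraries against 3 can give.

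Grm5, which encodes mGluR5, did not differ beyond the spread between libraries. It stood at 40.9 ± 0.938 CPM in the knockout and 45.0 ± 14.4 CPM in the wild type (SD, n = 3 each). The log2 fold change of Grm5 was -0.14 with a 95% interval from -0.65 to 0.38, so that a fold between 0.636 and 1.303 was not excluded (exact permutation p = 0.7). Its 3 knockout libraries lay close together, while the wild-type libraries ran from 29.9 CPM in library 13 to 58.5 CPM in library 17. Relative to the wild-type mean, the neuron marker medians rose alike, at -0.58, 0.21 and 0.37 in libraries 13, 15 and 17. In the knockout libraries these medians ran from -0.21 to 0.52 while Grm5 stayed between 39.9 and 41.5 CPM. Whether Grm5 reads came from neurons was not tested. Grm5 reversed its direction without wild-type library 17, to 0.098, and with the library month as a covariate, to 0.045. Without wild-type library 13 Grm5 was at -0.36 (unadjusted p = 0.0444 and adjusted p = 0.999 in edgeR's quasi-likelihood test). The 2 genes that host the miR-128 precursors did not pass either. R3hdm1 measured 40.6 ± 8.72 and 39.7 ± 8.81 CPM (log2 fold change 0.04, SE 0.22; 95% interval of the fold 0.726 to 1.45), and its direction also varied with the library left out, from -0.14 without wild-type library 13. Arpp21 measured 117 ± 11.6 and 107 ± 4.95 CPM (log2 fold change 0.14, SE 0.13; 95% interval of the fold 0.888 to 1.36), with adjusted p of 1.00 for both in edgeR's quasi-likelihood test. The mature miRNA itself was not analysed here.

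**Figure D2:**
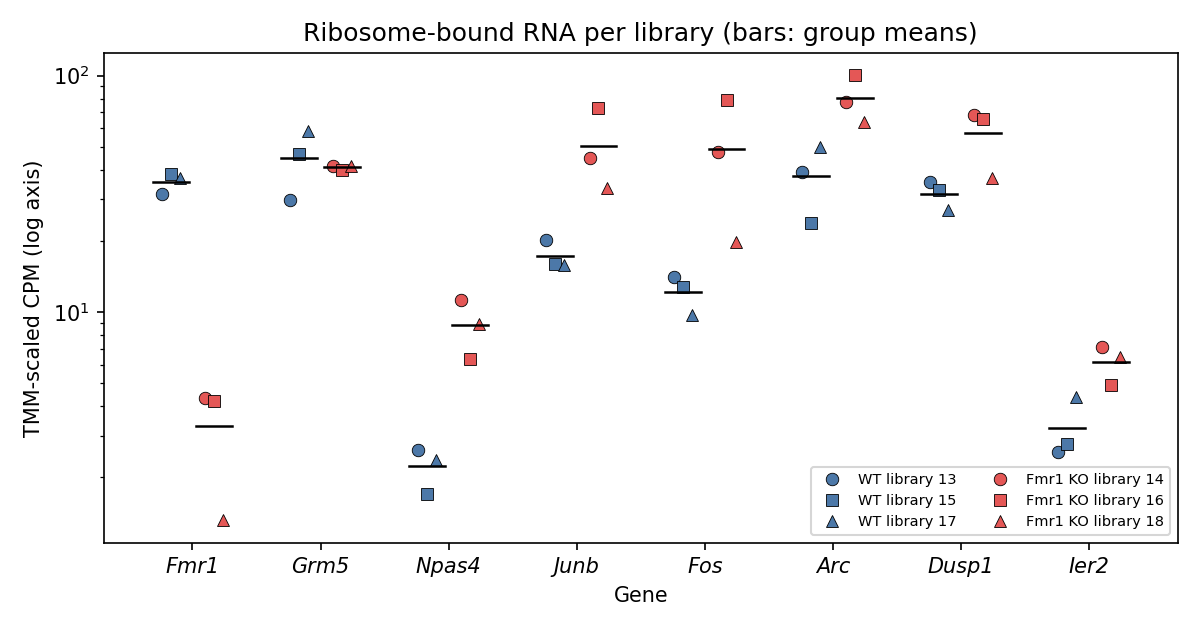
TMM-scaled CPM on a log axis for 8 genes, 1 point per library, with wild-type libraries in blue, knockout libraries in red and black bars at the group means. Fmr1 lies at 1.32 to 4.32 CPM in the knockout and 31.6 to 38.4 CPM in the wild type, while Npas4, Junb, Fos, Arc, Dusp1 and Ier2 are higher in each knockout library than in each wild-type library.

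Across all genes, those with the smallest p included activity-induced transcription factors and signalling genes on the higher side. Npas4, a neuronal activity-dependent transcription factor, measured 8.84 ± 2.46 CPM in the knockout and 2.22 ± 0.468 CPM in the wild type (SD, n = 3 each; log2 fold change 1.998, SE 0.30). Junb measured 50.3 ± 20.2 against 17.3 ± 2.49 CPM and Fos, its partner in the AP-1 factor, 48.7 ± 29.6 against 12.2 ± 2.18 CPM. On the lower side, Fgf1, a fibroblast growth factor, measured 102 ± 46.9 against 224 ± 16.6 CPM (log2 fold change -1.14, SE 0.29). Fn1, which encodes fibronectin, measured 7.84 ± 1.18 against 14.8 ± 1.99 CPM, and the potassium channel gene Kcnk2 measured 27.6 ± 2.33 against 39.7 ± 2.92 CPM.

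No gene passed the threshold in edgeR's quasi-likelihood test: 0 of 14990 genes, with 265 at an unadjusted p under 0.05 (110 higher and 155 lower in the knockout). These 265 are a smaller share of the tested genes than the 0.05 that chance gives without any change. Their number is therefore no evidence of changed genes. DESeq2 called 7 genes, 6 higher and 1 lower, edgeR's exact test 9 genes, 7 higher and 2 lower, and limma voom 0 genes with 300 at an unadjusted p under 0.05. The 7 calls of DESeq2 were among the 9 of the exact test. Fmr1 was lower in both, and Npas4 (DESeq2 adjusted p = 5.67e-05), Junb (DESeq2 adjusted p = 0.000243), Fos (DESeq2 adjusted p = 0.000566), Gm42742, Gm14434 and Gm26751 were higher. The exact test added Samd11, higher, and Pagr1a, lower. Gm42742, Gm14434, Gm26751 and Samd11 fall outside the rule for named genes and are named because these tests called them. The mean of Gm26751 was 2.04 CPM in the knockout and 0.244 CPM in the wild type.

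The 10 higher genes taken by rule had log2 fold changes from 0.53 to 1.998. Besides Npas4, Junb and Fos they were Arc (1.10, SE 0.28), Dusp1 (0.84, SE 0.24), Gng4 (0.64, SE 0.16), Rhebl1 (1.301, SE 0.33), Chd3os (0.53, SE 0.14), Tatdn3 (0.64, SE 0.19) and Clp1 (0.70, SE 0.21). Gng4 encodes a G protein gamma subunit and stood at 23.9 ± 1.75 against 15.3 ± 1.81 CPM (SD, n = 3 each). Chd3os is an antisense gene, and without a stated strand setting its reads cannot be told apart from those of its partner. The lower genes taken by rule included Fmr1, Fgf1, Fn1, Kcnk2, Pagr1a (-3.42, SE 0.67), Ctsc (-1.06, SE 0.23), Snhg6 (-1.33, SE 0.29), Rhoj (-0.86, SE 0.22) and Hacd4 (-1.28, SE 0.33). Ctsc, the gene of the lysosomal protease cathepsin C, stood at 3.51 ± 0.523 against 7.41 ± 0.468 CPM. Pagr1a measured 2.10 ± 1.66 against 20.6 ± 1.33 CPM and Gm42742 25.6 ± 5.288 against 4.46 ± 3.06 CPM, so that the pair summed to 27.7 ± 3.79 and 25.1 ± 1.81 CPM.

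Of the 28 gene lists, 2 passed the threshold with camera at the preset correlation of 0.01, 1 upward and 1 downward. The immediate early genes, which respond within minutes to activity and stress, passed upward: the median log2 fold change of its 15 members was 0.86, 13 members were higher in the knockout and camera's adjusted p was 3.58e-13. The call was lost with an estimated correlation (adjusted p = 0.183) and with fry (adjusted p = 0.118), and fry's test for changes in either direction gave an adjusted p of 0.0279. Of the 15 members 0 passed over all genes in edgeR's quasi-likelihood test, 7 passed when adjusted over the list alone and 9 had an unadjusted p under 0.05. Those 7 were Npas4, Junb, Fos, Arc, Dusp1, Ier2 and Fosb. In 8 members each knockout library was above each wild-type library and in 0 each was below, where chance gives 10% of genes no overlap counting both directions. The members come from the same libraries and are not independent, so this count is not a test. Ier2 measured 6.16 ± 1.11 against 3.23 ± 0.988 CPM, and Nr4a1 36.2 ± 18.1 against 20.05 ± 4.71 CPM (SD, n = 3 each), whereas Nr4a3 was at 7.14 ± 0.530 against 10.3 ± 4.43 CPM.

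The higher level of the immediate early genes was uneven across libraries. Relative to the wild-type mean, the list median was 1.08 and 1.2004 in knockout libraries 14 and 16, which hold the large ribosomal RNA share, and 0.34 in knockout library 18. Within month 5, knockout libraries 14 and 16 stood against 0.13 in wild-type library 13, and within month 6 knockout library 18 stood against -0.11 and 0.08 in wild-type libraries 15 and 17. With month as a covariate the list median was 0.61 (camera adjusted p = 1.70e-08, and 0.469 with an estimated correlation). The list median was 0.51 with the ribosomal RNA share as a covariate, and 0.29 without libraries 14 and 16, which leaves 1 knockout library. Without covariate the neuron markers had a median log2 fold change of 0.095 (camera adjusted p = 0.459) and the heat shock and unfolded protein genes one of 0.02 (camera adjusted p = 0.915).

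The microglia markers passed downward, with a median log2 fold change of -0.26 over 19 members, of which 16 were lower (camera adjusted p = 0.00956). That call was also lost with an estimated correlation (adjusted p = 0.294), with fry (adjusted p = 0.118) and without knockout library 18 (camera adjusted p = 0.123), where the median stayed at -0.25. With the ribosomal RNA share as a covariate, a fit added after the data were seen, the list passed downward with fry (median -0.32, fry adjusted p = 0.0321) and was lost with an estimated correlation (adjusted p = 0.659). Of its 19 members 0 passed over all genes, 0 passed when adjusted over the list alone, and 1 had an unadjusted p under 0.05. That 1 was C1qc, a complement gene, at 1.76 ± 0.914 against 4.49 ± 1.5002 CPM (SD, n = 3 each). Fcrls measured 1.32 ± 0.0644 against 2.77 ± 1.55 CPM and Csf1r 8.13 ± 1.96 against 9.77 ± 0.114 CPM, whereas Aif1 was at 2.33 ± 1.07 against 1.61 ± 0.294 CPM.

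Markers of the other cell types did not pass in the fit on genotype alone, and several passed in other fits at the preset correlation only. In that fit the median log2 fold change was -0.0047 for astrocytes, 0.07 for oligodendrocytes, 0.08 for oligodendrocyte precursors, -0.02 for endothelial cells, 0.03 for mural cells and fibroblasts, -0.29 for choroid plexus and ependyma and 0.27 for the 5 blood cell genes, with camera's adjusted p between 0.209 and 0.915. Camera's direction or the mean differed in sign from the median for the astrocyte markers, the mural and fibroblast markers, the cytosolic ribosomal proteins, the clock genes and the glucocorticoid and metallothionein genes. The astrocyte filament gene Gfap measured 2435 ± 245 against 2252 ± 342 CPM (SD, n = 3 each). Olig2, an oligodendrocyte lineage factor, measured 34.5 ± 5.01 against 27.2 ± 3.38 CPM, and the interneuron peptide Vip 22.9 ± 6.63 against 34.3 ± 9.99 CPM. With month as a covariate the neuron markers (median 0.36, camera adjusted p = 6.39e-08), the oligodendrocyte markers (0.29, camera adjusted p = 0.00319) and the blood cell genes (0.89, camera adjusted p = 0.00225) passed upward. Without wild-type library 17, camera's adjusted p was 0.0314 for astrocyte and 0.0102 for choroid plexus and ependymal markers, both downward, and 0.00301 for neuron markers, 0.0456 for oligodendrocyte precursor markers and 0.0275 for blood cell genes, all upward. The neuron markers also passed upward without knockout library 16 (camera adjusted p = 0.0228) and the blood cell genes without knockout library 14 (camera adjusted p = 0.0332). The oligodendrocyte markers passed upward without knockout library 16 (camera adjusted p = 2.65e-05) and downward without knockout library 18 (camera adjusted p = 0.0224). All of these calls were lost with an estimated correlation (camera adjusted p of at least 0.469), and fry kept only the blood cell genes with month as a covariate (fry adjusted p = 0.0203). Neuron markers varied more within a genotype than between: the list median ran from -0.58 in library 13 to 0.37 in library 17 among wild-type libraries and from -0.21 in library 16 to 0.52 in library 18 among knockout libraries.

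**Figure D3:**
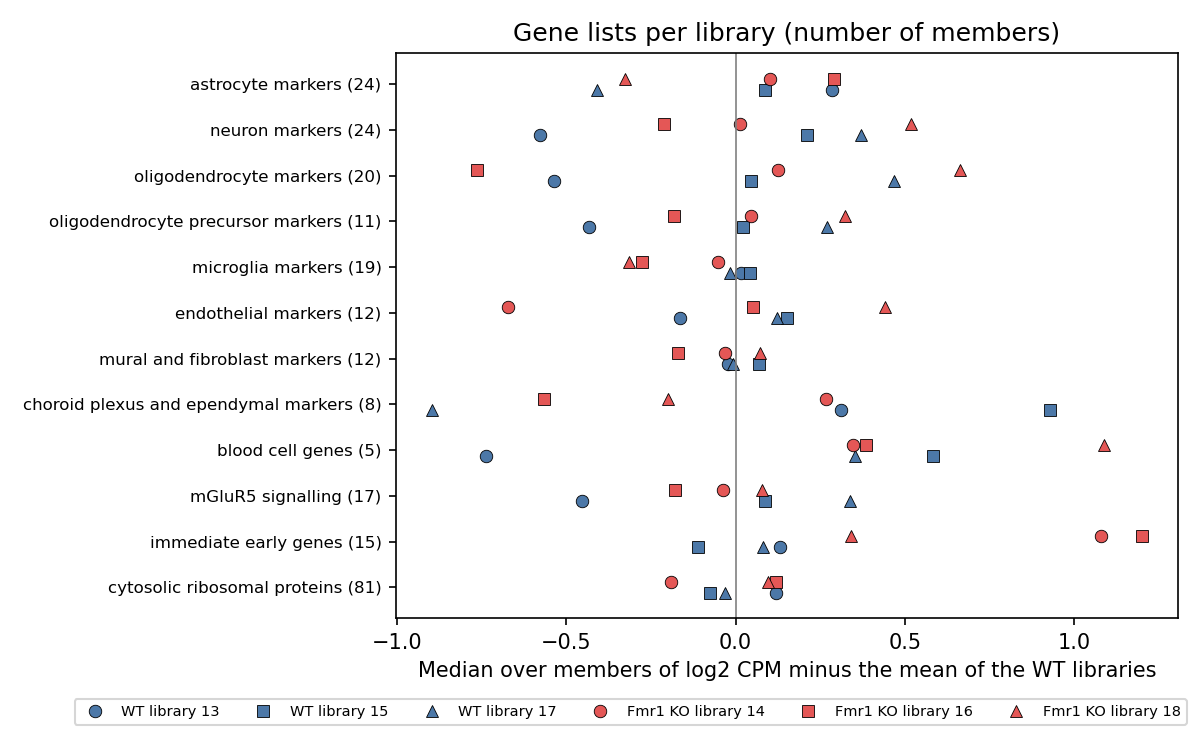
For 12 gene lists, the median over members of log2 CPM minus the mean of the wild-type libraries (horizontal axis), 1 point per library, with wild type in blue and knockout in red. The immediate early genes lie at 0.34 to 1.2004 in the knockout libraries and at -0.11 to 0.13 in the wild-type libraries, whereas the neuron and oligodendrocyte markers of the genotypes overlap.

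The mGluR5 signalling genes, 17 of which were measured, had a median log2 fold change of -0.06 with 11 lower and 6 higher, and did not pass (camera adjusted p = 0.459). None of the 17 passed over all genes or when adjusted over the list alone in edgeR's quasi-likelihood test (0 at an unadjusted p under 0.05). The Homer genes, scaffolds that bind mGluR5, had the smallest p of this list: Homer2 measured 13.8 ± 1.85 against 19.4 ± 6.91 CPM, Homer3 21.6 ± 1.93 against 26.3 ± 3.30 CPM and Homer1 99.7 ± 22.7 against 113 ± 5.98 CPM (SD, n = 3 each). Without wild-type library 13 the list passed downward (camera adjusted p = 0.0102, and 0.933 with an estimated correlation), and without wild-type library 17 its direction turned upward (camera adjusted p = 0.794).

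Astrocyte function lists lay near 0 in the fit on genotype alone. The median log2 fold change was -0.01 for glutamate and GABA handling, with Grm3 at 200 ± 56.7 against 238 ± 48.3 CPM (SD, n = 3 each), -0.02 for potassium, water and gap junction genes, -0.06 for synapse-regulating genes and -0.06 for cholesterol synthesis. In the last list Hsd17b7 measured 14.2 ± 1.24 against 20.4 ± 4.98 CPM and Hmgcs1 433 ± 19.2 against 489 ± 25.6 CPM. Reactive astrocyte genes had medians of -0.33 (pan-reactive), -0.04 (A1) and -0.07 (A2). Among them Cd44 measured 6.84 ± 1.95 against 10.04 ± 2.57 CPM, Aspg 13.1 ± 3.17 against 8.31 ± 3.19 CPM, and S100a10 7.50 ± 2.23 against 39.5 ± 31.0 CPM, the latter with wild-type libraries at 39.985, 8.29 and 70.2 CPM. Camera's adjusted p was between 0.459 and 0.915 for these lists. Cholesterol synthesis passed downward with month as a covariate (median -0.13, camera adjusted p = 0.0368) and without wild-type library 17 (camera adjusted p = 0.0169), as did the potassium, water and gap junction genes without wild-type library 17 (camera adjusted p = 0.0275). These calls were lost with an estimated correlation (camera adjusted p of at least 0.669) and with fry (adjusted p of at least 0.783).

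Transcripts reported as FMRP targets did not pass as a group on genotype alone. In the fit on genotype alone the 26 measured had a median log2 fold change of 0.03, 15 higher and 11 lower (camera adjusted p = 0.618), with Arc, shared with the immediate early list, the 1 member at an unadjusted p under 0.05. They passed upward with month as a covariate (median 0.22, camera adjusted p = 9.84e-05) and without wild-type library 17 (camera adjusted p = 0.00697) at the preset correlation. Both calls were lost with an estimated correlation (camera adjusted p = 0.687 and 0.669) and with fry (adjusted p = 0.495 and 0.832). Grin2b measured 90.8 ± 19.6 against 123 ± 60.2 CPM (SD, n = 3 each). The 10 genes of FMRP relatives and partners had a median of -0.03. The remaining medians were 0.01 for 81 cytosolic ribosomal proteins, where Rpl10a measured 342 ± 12.7 against 440 ± 74.7 CPM, 0.01 for 75 nuclear-encoded oxidative phosphorylation genes, 0.17 for 9 mitochondrially encoded genes, 0.01 for clock genes, -0.03 for glucocorticoid and metallothionein genes, 0.27 for long noncoding RNAs and -0.05 for strain-variable genes. Rpl10a was the 1 ribosomal protein gene at an unadjusted p under 0.05 in edgeR's quasi-likelihood test. It was also the 1 such gene with each knockout library below each wild-type library. Examples from the other lists were Per1 at 15.2 ± 1.36 against 20.3 ± 2.78 CPM and Mt2 at 1005 ± 117 against 1306 ± 244 CPM. Malat1 was at 374 ± 61.5 against 313 ± 81.5 CPM and Nnt at 17.1 ± 6.15 against 28.2 ± 12.8 CPM. Camera's adjusted p was between 0.209 and 0.915 for these lists without a covariate. Among the strain-variable genes, H2-T22 varied within each genotype. It was at 11.8, 0.355 and 18.4 CPM in wild-type libraries 13, 15 and 17. In knockout libraries 14, 16 and 18 it was at 1.06, 2.68 and 11.1 CPM. The median of that list therefore does not show whether strain background varied between libraries. With month as a covariate the mitochondrially encoded genes (camera adjusted p = 0.0342) and the long noncoding RNAs (camera adjusted p = 0.000538) passed upward, as they did without wild-type library 15 (camera adjusted p = 0.0292 for both) and without wild-type library 17 (camera adjusted p = 0.00676 and 0.00449). The cytosolic ribosomal proteins passed upward without knockout library 14 (camera adjusted p = 0.000823) and the nuclear-encoded oxidative phosphorylation genes without wild-type library 13 (camera adjusted p = 0.000353). These calls too were lost with an estimated correlation (camera adjusted p of at least 0.655) and with fry (adjusted p of at least 0.495).

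Genes near Fmr1 on chromosome X were examined because a knockout chromosome can carry flanking sequence of another strain. Of 77 tested neighbours within 10 Mb 0 passed the threshold and 0 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test, against 236 of 13940 placed genes elsewhere (1.69%). Fisher's exact test on the unadjusted calls, chosen because 0 genes passed the threshold, gave a two-sided p of 0.643. Two-sided values for windows of 5 Mb and 20 Mb were 1 and 0.429 by the same exact test.

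The authors' deposited table holds 85 genes at an adjusted p under 0.05, 40 higher and 45 lower in the knockout, and 1027 at an unadjusted p under 0.05. Of the 85 genes called in the authors' deposited table, a total of 69 were tested here, and all 69 had the same direction and an unadjusted p under 0.05 in edgeR's quasi-likelihood test. Of these genes 0 passed that test's threshold, 6 passed with DESeq2 and 8 with edgeR's exact test. The log2 fold changes of the authors' deposited table and those here correlated at 0.998 across genes, which are not independent replicates. Both come from the same libraries, so neither the shared direction nor this correlation is independent evidence. In the authors' deposited table Fmr1 has an adjusted p of 4.05e-40, Junb and Npas4 4.11e-11, Fos 3.11e-08 and Arc 4.54e-05.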

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

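The miR-128 seed-site alternatives were not run, because no transcript sequences were used here. Tests chosen after the data were seen are edgeR's exact tests, the robust quasi-likelihood test, leaving out the ribosomal RNA features, leaving out libraries 14 and 16 together, the ribosomal RNA share or the neuron marker level as a covariate, and the estimated correlation and fry in fits other than the main one. The cause of a change was not tested except where stated. The count of 0 genes became 14 with each entry as its own sample, which doubles the samples, 1 with the second entries alone, 7 with DESeq2, 6 without a low-count filter, 9 with the exact test, 94 with the classic exact test on 12 entries, 1 with the ribosomal RNA share and 2 with the neuron marker level as covariate. Without 1 library it lay between 0 and 2, with 2 without knockout library 18 and 1 without wild-type library 15. The count of genes shared with the deposited comparison became 13, 6, 8 and 83 with entries as samples, DESeq2, the exact test and the classic exact test on 12 entries. Fmr1 stayed lower in all settings and passed with entries as samples (-3.61), DESeq2 (-3.50), no filter (-3.54), the exact test (-3.49), the classic exact test on 12 entries (-3.58), the ribosomal RNA share (-4.20) and the neuron marker level (-3.61) as covariate. Without 1 library its log2 fold change lay between -3.86 and -3.06, and it passed without knockout library 18. Grm5 reversed to 0.045 with month as covariate and lay between -0.36 and 0.098 without 1 library.

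The 2 gene lists became 9 with month as covariate, 12 without libraries 14 and 16, which leaves 1 knockout library that is assumed to vary like the wild-type libraries, 5 with the ribosomal RNA share as covariate, 4 with the neuron marker level, and 0 with an estimated correlation and with fry. They lay between 2 and 12 without 1 library, with 12 without wild-type library 17, 2 without knockout library 18 and 4 without each of the others. In these fits the estimated correlation called 0 lists, and fry 1 with month (blood cell genes) and 1 with the ribosomal RNA share as covariate (microglia markers). For the immediate early genes the adjusted p was 0.183 with an estimated correlation and 0.118 with fry, for the microglia markers 0.294 and 0.118. Without 1 library the microglia p lay between 0.00697 and 0.123 and the immediate early p between 4.50e-13 and 6.67e-07. The mGluR5 signalling list turned upward, not past the threshold, with month as covariate (adjusted p = 0.540) and without libraries 14 and 16 (0.635), and its adjusted p lay between 0.0102 and 0.873 without 1 library. Of 1143 pairs of a setting and a named gene other than Fmr1 and Grm5, 1080 kept side and direction, 57 passed the threshold in the alternative alone, and 6 reversed. These were R3hdm1 with second entries (-0.055), with the ribosomal RNA share (-0.013) and without knockout library 14 or wild-type library 13, with a range from -0.14 to 0.18 over the settings without 1 library, and, without libraries 14 and 16, Aif1 (-0.14) and Gfap (-0.0085). Depth is lowest in knockout library 16, which limits genes near 1 CPM most.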

Other observations

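The splits of the libraries and the fit with month as a covariate were chosen before the data were seen. The comparison between months, the tests of neuron markers and of the ribosomal RNA share, the summed pair, the classic exact tests, the share in 1 library, and the estimated correlation and fry between months and in the splits were chosen after the results they bear on were seen. The month in the library names gave more genes at a low unadjusted p than genotype did, as did several other splits of the libraries. Libraries 14, 17 and 18 against the rest, a split by neither, gave 1678 genes at an unadjusted p under 0.05 and 13 lists at the preset correlation. Wild-type library 13 and knockout libraries 14 and 16 carry month 5, and wild-type libraries 15 and 17 and knockout library 18 carry month 6. Month 5 thus holds both libraries with the large ribosomal RNA share, so month cannot be told apart from that share. Between months edgeR's quasi-likelihood test gave 1 gene past the threshold, Gm6505, and 2457 genes at an unadjusted p under 0.05, which is 16.4% of those tested. By camera at the preset correlation of 0.01, 13 of the 28 lists passed, but 0 passed with an estimated correlation (adjusted p of at least 0.536) or with fry (adjusted p of at least 0.216). In month 6 over month 5 the median log2 fold change and camera's adjusted p at the preset correlation were 0.63 and 1.85e-08 for neuron, 0.69 and 3.44e-08 for oligodendrocyte, 0.76 and 0.0138 for endothelial and -0.43 and 5.99e-07 for astrocyte markers. They were 0.49 and 5.99e-07 for FMRP-bound transcripts, 0.44 and 0.00163 for mGluR5 signalling, -0.62 and 0.0310 for immediate early genes, and 0.03 and 0.799 for microglia markers. With month as a covariate, genotype gave 0 genes past the threshold in edgeR's quasi-likelihood test, 709 at an unadjusted p under 0.05, and 9 lists at the preset correlation, 0 with an estimated one and 1 with fry.

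The 6 libraries have 10 splits into 3 and 3, so the share of splits cannot fall under 0.05. Genotype gave 0 genes in edgeR's quasi-likelihood test (265 at an unadjusted p under 0.05), which every split reaches, and another split at most 2. It gave 2 lists at the preset correlation, and the other splits gave from 2 to 13. The absolute median of the immediate early genes was 0.86 for genotype and at most 0.62 in another split, the split by month, and genotype was the 1 split that reached it. For the microglia markers it was 0.26 against at most 0.15, again with 1 split reaching it. These 2 lists are the ones that the genotype fit called. That choice favours genotype in this comparison, so its larger medians are no separate support. With an estimated correlation or with fry, all 10 splits gave 0 lists, so list calls at the preset correlation also arise in splits that do not follow genotype and are weak evidence on their own.

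The higher immediate early genes in the knockout libraries may have a technical source. More RNA from neurons is argued against as the whole cause in knockout libraries 14 and 16. Relative to the wild-type mean, their immediate early medians were 1.08 and 1.2004, and their neuron marker medians 0.014 and -0.21. Neuron marker medians of the wild-type libraries ran from -0.58 to 0.37. In the fit on genotype alone the neuron markers had a median of 0.095 (SE 0.04 over markers) against the 0.86 (SE 0.18) of the list. These SEs do not measure the spread between libraries, since members move together, with an estimated correlation of 0.72 for the neuron markers. The list median was 0.80 with the neuron marker level as a covariate. With month as a covariate the medians lay closer together, at 0.36 for the neuron markers and 0.61 for the list, and in knockout library 18 the neuron markers were at 0.52 and the list at 0.34, so a part stays open. The share of ribosomal RNA cannot be told apart from genotype as the cause, as knockout libraries 14 and 16 have both the large share and the highest medians. With that share as a covariate the list median fell from 0.86 to 0.51, 13 of 15 members were higher, and fry gave an unadjusted p of 0.0377 and an adjusted p of 0.527. Without libraries 14 and 16 the median was 0.29, with 1 knockout library that is assumed to vary like the wild-type libraries. Handling on the day and higher activity of neurons or astrocytes in the knockout stay open as untested, since each library has its own date.

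The opposite values of Pagr1a and Gm42742 could come from reads divided differently between features of shared sequence. The summed count of the pair had a log2 fold change of 0.15 (SE 0.15), while Pagr1a had -3.42 and Gm42742 2.53. The reference used here places Pagr1a on chromosome 7 and gives no position for Gm42742, so this cannot be told apart from separate changes of both.

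The 85 genes of the authors' deposited table against 0 here may follow from counting the 2 entries of a library as separate samples. The classic exact test called 94 genes on the 12 entries and 14 on the 6 summed libraries under the same filter rule, 13 of them shared. The choice between an exact and a quasi-likelihood test also moved the count, as 9 against 0 genes on the summed libraries shows. Of the 85 genes called in the authors' deposited table, 8 had at least 80% of their summed CPM, before TMM scaling, in 1 library of the count table. Shox2, named after its values were seen, was at 11.5 CPM before TMM scaling in wild-type library 15 and 0 in the other libraries.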
